A study of Fragaria vesca with 12 samples.

How the data were processed

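The labels describe 12 libraries of strawberry fruit in 4 groups of 3: input and anti-m6A IP of WT and of the Fvalkbh10b mutant. Per the labels' protocols, mRNA was isolated from total RNA and fragmented, part was precipitated with an antibody against m6A, and both parts were made into libraries and sequenced in pairs. The submitters' processing notes name FastQC, HISAT2 and StringTie without version or role. The genome build, the annotation and the peak caller are not given in the sources used here. Gene identifiers have the FvH4 form and chromosomes are numbered 1 to 7 with further contigs.

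The expression table holds FPKM, fragments scaled to transcript length and to mapped fragments, computed by the authors per the file headers and rounded to 2 decimals. It also holds the log2 fold change, p-value and q-value deposited by the authors for each gene. The deposited log2 fold change was within 0.02 of the log2 ratio of the mean FPKM in 99.8% of 10476 genes with a mean over 5. Of the genes with a mean over 5, those with p over 0.9 in the authors' deposited table had log2 fold changes of 0.25 to 0.34, so the test behind that column is centred away from 0; the test is not given in the sources used here. The genes the authors marked as significant, 5154 in the authors' deposited table, have p of at most 0.05 and a change of at least 2-fold. The 3 peak tables hold positions, the log2 ratio of IP over input (or of its change between genotypes) and p-values deposited by the authors, rounded to 2 decimals. Per the file headers each genotype has 1 list of confident peaks from the replicate experiments, so there are no values per IP library. Peak enrichments were used to describe, filter and class peaks within their own list, and no test compared them between lists. To check what the differential column holds, the deposited log2 change was set against the difference of the deposited enrichments on 1136 intervals identical in the 3 tables (Pearson r = 0.998 across intervals, which are not independent replicates). No column of per-sample values was left unmapped.

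Peak starts count from 0 in the deposited tables. Of the WT peaks, 3704 start 1 base before the start of their gene in the expression table and 0 start exactly at it. Starts were therefore raised by 1, and lengths were taken from the converted bounds, since the peak length deposited by the authors counts 1 base more. No genome of this build was given, so sequence motifs in peaks were not analysed here, and the gene table of another assembly was not used.

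Low FPKM values showed no steps of whole reads, so read counts could not be recovered and the depth is unknown; no count model was used. Genes with a mean of at least 1 FPKM over the 6 input libraries (15571) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genotype as the only term, a mean-variance trend, and Benjamini-Hochberg adjustment. Fold changes on this scale understate the change of low genes. An FPKM of 0 can be a failed estimate, so such values are given as listed. On simulated data of the same 15571 genes and 3 against 3 libraries, 67 genes were changed by 0.5 log2 units, 67 by 1 and 66 by 2. The step recovered 47.8%, 86.6% and 100% of these and called 2 unchanged genes. Far fewer genes were changed there than the 10505 called in the data. The adjustment was therefore stricter in the simulation, and these rates do not carry over to the data. The 16 gene lists were word patterns on the gene descriptions, tested with camera at a preset correlation of 0.01. On simulated lists camera called the 1 moved list and 0 of the others. The simulated genes were drawn independently, so this does not show how camera treats lists whose genes vary together. With an estimated correlation 0 lists passed camera, and 2 did at an unadjusted p under 0.05. The lists covered the m6A machinery, abscisic acid, flavonoids and anthocyanins, cell wall remodelling, sugars, aroma compounds, auxin, gibberellin, ethylene, MADS-box and NAC factors, photosynthesis, achene and seed markers, lignified vascular tissue, heat and stress chaperones, defence proteins and cytosolic ribosomal proteins.

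Genes were named by a rule fixed before the data were examined. It took the m6A machinery, the 8 largest rises and 8 largest falls among genes past adjusted p 0.05 with a mean of at least 5 FPKM in one genotype, separate libraries and a named protein, and up to 3 members of each list with the smallest adjusted p. For peaks it took the 6 largest rises and 6 largest falls with a named protein and a mean input of at least 1 FPKM, up to 2 differential peaks per list, and the 6 genes with the smallest peak p that passed both tests. The text gives a selection of these. The peaks taken are all listed with a p of 0, so p alone could not rank them, and the rule gave no order for ties. Outside the rule, FvH4_2g24110 was added after its values were seen. So were FvH4_6g13160, FvH4_2g20470, FvH4_5g26480, FvH4_3g20030 and list members that changed direction after rescaling or quantile normalization.

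Overlaps and RNA comparisons used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and matplotlib 3.10.9 for plots. Differential peaks were taken at the authors' adjusted p under 0.05. Genes with peaks in both directions were left out of the RNA comparison, which used permutation tests on ranks with 100000 resamples and Fisher's exact test, both two-sided. The background was the 13573 tested genes with a peak in either genotype. Alternatives fixed before the data were examined covered the pseudocount, the filter, the scaling, the mean-variance trend, the replicate number as a block, each library left out, the authors' own calls, and the thresholds and overlaps of peaks.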

Results

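The study profiled N6-methyladenosine (m6A), a methyl mark on adenosines of mRNA, in fruit of the diploid strawberry Fragaria vesca. Fruit of wild-type (WT) plants and of the Fvalkbh10b mutant were taken at 27 days post anthesis (DPA). ALKBH10B belongs to the AlkB family of dioxygenases, of which some members remove m6A from mRNA. The 12 samples formed 4 groups of 3 biological replicates: input RNA and anti-m6A immunoprecipitated RNA (IP) of each genotype. Input values were FPKM of 21927 genes in each of the 6 input libraries. The IP libraries entered only through lists of enriched regions (peaks) made by the authors, with 1 list per genotype and a table of differential peaks. The FPKM gave no read numbers, so the depth of each library is unknown. The summed FPKM lay between 467174 and 522590 per library. Replicates of a genotype were close, with Pearson correlations across genes of 0.991 to 0.993, against 0.895 to 0.897 between genotypes.

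The first comparison asked whether the targeted gene differed between the genotypes. No gene description in the files names ALKBH10B, so its level could not be read by name. A single gene is annotated with RNA N6-methyladenosine dioxygenase activity, the uncharacterized gene FvH4_2g24110 (chromosome 2, 19702086 to 19706888, plus strand), and it was singled out after its values were seen. Its input RNA was 30.27, 28.53 and 31.03 FPKM in the WT libraries and 3.75, 3.84 and 5.34 FPKM in the mutant libraries. The log2 change was -2.55 ± 0.11 (SE, n = 3 per genotype, limma adjusted p = 3.01e-08), and the exact two-sided permutation test gave 0.1, the smallest p that 3 against 3 libraries allow. Whether this gene is the one mutated is not given in the sources used here. A different gene described as RNA demethylase ALKBH5, FvH4_1g11920, stood at 18.5 ± 1.15 FPKM in WT and 21.9 ± 2.36 in the mutant (SD, n = 3). Its adjusted p of 0.0418 became 0.685 after the libraries were rescaled to one median.

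Input RNA differed widely between the genotypes. Most genes of the photosynthesis list and the auxin response genes IAA14-like and IAA16 were higher in the mutant. An exopolygalacturonase-like gene, beta-galactosidase 16, a pair of BAHD acyltransferase genes and the transcription factor NAC domain-containing protein 8 were lower. Of 15571 genes tested, 7527 were higher and 2978 lower in the mutant (limma, adjusted p under 0.05). With a change of at least 2-fold on the log2(FPKM + 1) scale as a further condition, 2173 were higher and 1011 lower. The median log2 change of all tested genes was 0.25 in favour of the mutant, so list medians are given relative to it. After rescaling each library to one median, 4800 genes were higher and 5011 lower, so the balance of directions rests on the scaling; at 2-fold it was 1574 higher and 1318 lower.

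The largest rises by the fixed rule included probable pectate lyase 5 (FvH4_4g25110), which cleaves pectin, at 2.02 ± 0.513 FPKM in WT and 529 ± 16.5 in the mutant (SD, n = 3). Plastocyanin (FvH4_2g37890), an electron carrier of photosynthesis, went from 1.15 ± 0.837 to 222 ± 3.02 FPKM. Peroxidase 42 (FvH4_3g02090) went from 20.1 ± 1.11 to 1316 ± 17.0 FPKM, and EXORDIUM-like 3 (FvH4_7g27970) from 4.18 ± 0.737 to 308 ± 4.61 FPKM. The largest falls were led by a vinorine synthase-like gene (FvH4_7g18570), with 3318 ± 26.6 FPKM in WT and 1.62 ± 0.343 in the mutant. An exopolygalacturonase-like gene (FvH4_6g41380), of a family that degrades pectin, had 2035 ± 30.7 FPKM in WT and 0.870 ± 0.225 in the mutant. Beta-galactosidase 16 (FvH4_2g27470) fell from 759 ± 8.69 to 1.07 ± 0.103 FPKM. A pair of BAHD acyltransferase genes, FvH4_7g18640 and FvH4_6g40060, stood at 1139 ± 27.4 and 640 ± 8.33 FPKM in WT and at 0.273 ± 0.159 and 0.0867 ± 0.0416 in the mutant. Probable mannitol dehydrogenase (FvH4_1g19281) fell from 498 ± 8.78 to 0.480 ± 0.111 FPKM. The limma adjusted p of these genes was at most 2.1e-09. Members of such families may share reads with close copies, so the level of any one copy is uncertain.

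Photosynthesis was the list with the clearest shift. Of 39 members tested, 38 rose and 1 fell, 35 of them rising by at least 2-fold, and the same 38 and 1 passed when adjusted over the list alone. The list median lay 3.31 log2 units above that of all genes (camera adjusted p = 7.73e-14; adjusted p = 0.0528 with an estimated correlation). Photosystem I subunit N (FvH4_1g24360) had 0.0700 ± 0.0436 FPKM in WT and 140 ± 12.8 in the mutant. A chlorophyll a-b binding protein (FvH4_6g38460), which gathers light, rose from 13.2 ± 0.293 to 288 ± 11.6 FPKM, and photosystem I subunit XI (FvH4_6g00530) from 7.34 ± 0.210 to 149 ± 9.75. The member that fell was a ribulose bisphosphate carboxylase/oxygenase activase gene (FvH4_6g13160), with a log2 change of -1.20 ± 0.10 (SE), and it was named after its values were seen.

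Cell wall remodelling genes moved both ways, with a balance toward lower RNA. Of 88 members, 45 fell and 37 rose, 30 and 21 of them by at least 2-fold, and counts adjusted over the list alone were the same. The list median was -0.48 log2 units from that of all genes (camera adjusted p = 1.41e-04; adjusted p = 0.252 with an estimated correlation). Probable pectate lyase 8 (FvH4_4g05760) fell from 2730 ± 54.7 FPKM in WT to 95.9 ± 4.10 in the mutant, while probable pectate lyase 5 rose as given above. Achene and seed markers fell more often than they rose, 17 against 8 of 30 (camera adjusted p = 5.06e-04; adjusted p = 0.0911 with an estimated correlation), and the counts adjusted over the list alone were the same. A 12S seed storage protein (FvH4_5g29270) was listed at 196.65, 191.81 and 194.52 FPKM in WT and at 0.06, 0 and 0.22 FPKM in the mutant. A vicilin-like gene (FvH4_1g13730) fell from 28.0 ± 1.65 to 3.04 ± 0.115 FPKM. The word pattern of this list also took in 5 GEM-like proteins, which are not seed storage proteins; one, GEM-like protein 5 (FvH4_4g23040), fell from 155 ± 3.75 to 13.9 ± 2.40 FPKM. Of these 5, 3 fell and 1 rose. Without them 14 of 25 members fell and 7 rose (adjusted p = 0.00504, an alternative chosen after seeing the data).

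**Figure D1:**
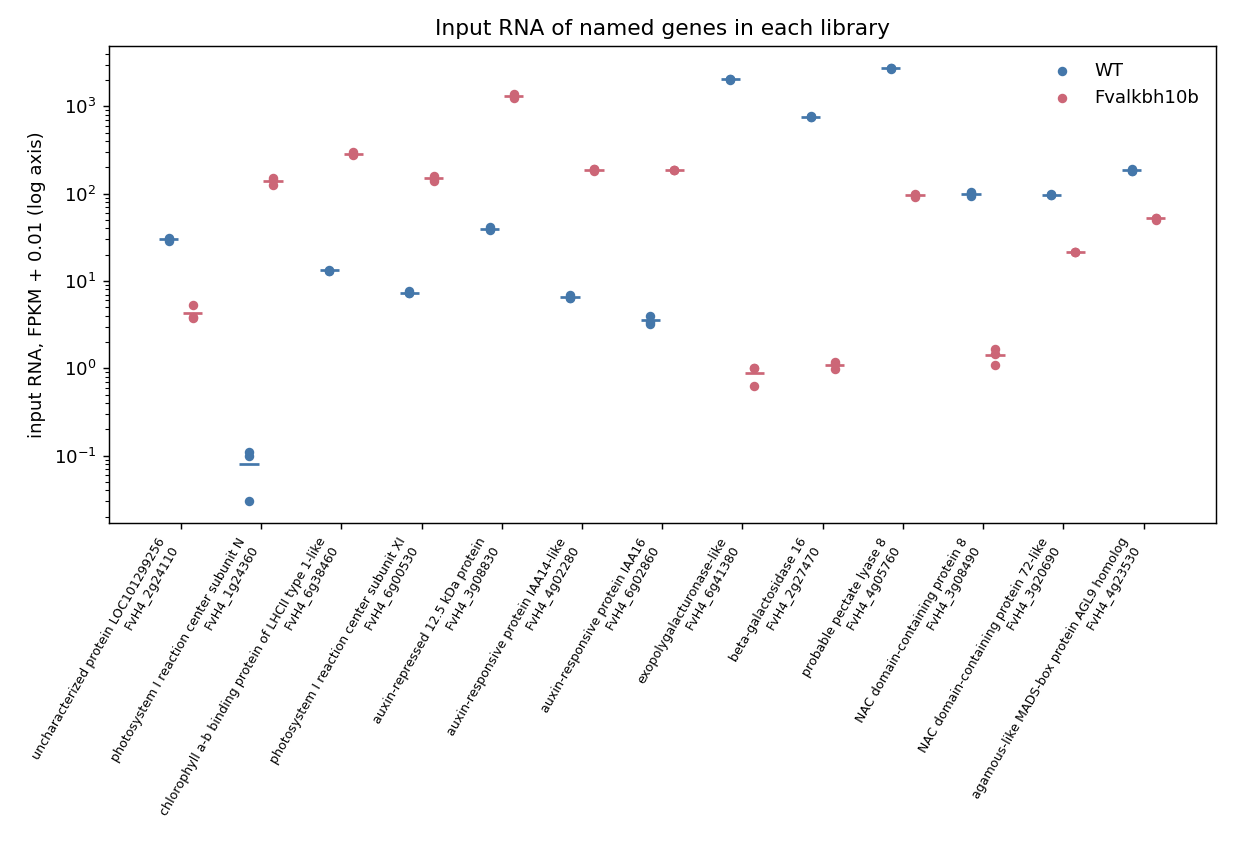
Input RNA of 13 named genes in each library, as FPKM plus 0.01 on a log axis; points are the 3 libraries of a genotype and bars their means. The plotted photosynthesis and auxin genes lie higher in Fvalkbh10b, and FvH4_2g24110 and the plotted cell wall, NAC and MADS-box genes lower, with no overlap between genotypes.

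Flavonoid and anthocyanin genes were split evenly, with 21 of 47 rising and 21 falling, the same as adjusted over the list alone. Their median was -0.04 from that of all genes and the camera adjusted p was 0.0535. The raw median was above 0 and the mean below it. Camera, which compares a list with the other genes, placed this list lower. The list passed without Fvalkbh10b input replicate 1 (adjusted p = 0.0477) or replicate 2 (0.0459), and the camera alternatives ranged from 0.0459 to 0.350. Anthocyanidin 3-O-glucosyltransferase 2 (FvH4_7g33840), which attaches a sugar to anthocyanidins, fell from 146 ± 3.46 to 1.26 ± 0.316 FPKM. Anthocyanidin reductase (FvH4_3g02980), which leads toward proanthocyanidins, rose from 10.7 ± 0.179 to 135 ± 4.53 FPKM, and a flavonol synthase (FvH4_5g20432) from 1.08 ± 0.168 to 96.1 ± 2.78. Of 34 MADS-box and NAC transcription factors, 12 rose and 13 fell, the same as adjusted over the list alone (camera adjusted p = 0.0535). That list passed without Fvalkbh10b input replicate 2 (adjusted p = 0.0459) or WT input replicate 3 (0.0475), in a range of 0.0459 to 0.298. NAC domain-containing protein 8 (FvH4_3g08490) fell from 99.9 ± 6.09 to 1.40 ± 0.298 FPKM and the MADS-box gene AGL9 homolog (FvH4_4g23530) from 185 ± 5.87 to 52.2 ± 1.64.

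None of the 4 hormone lists passed as a list, while single members changed strongly. In the auxin list 40 of 67 members rose and 22 fell (camera adjusted p = 0.742). The auxin-repressed 12.5 kDa protein (FvH4_3g08830) rose from 39.9 ± 1.43 to 1312 ± 71.8 FPKM, and IAA14-like (FvH4_4g02280) and IAA16 (FvH4_6g02860), repressors of auxin response, rose from 6.61 ± 0.283 to 187 ± 3.94 and from 3.52 ± 0.401 to 189 ± 0.265. Of 30 abscisic acid genes, 18 rose and 8 fell (camera adjusted p = 0.928, in the lower direction against the other genes). Their median was above 0 and their mean below it. Among those that fell were the receptor PYL2 (FvH4_2g32040), from 22.1 ± 0.789 to 1.60 ± 0.286 FPKM, and protein phosphatases 2C 51 (FvH4_7g31810) and 24 (FvH4_3g37010), from 55.4 ± 2.66 to 1.77 ± 0.557 and from 26.0 ± 0.395 to 0.787 ± 0.297. Ethylene genes gave 40 higher and 20 lower of 67 (camera adjusted p = 0.742), and 1 member, the transcription factor RAP2-3 (FvH4_4g18780), was called higher before and lower after rescaling. Gibberellin genes gave 9 higher and 6 lower of 17 (camera adjusted p = 0.742, in the lower direction against the other genes). Their median and mean were above 0. Counts adjusted over each of these 4 lists alone were the same.

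Sugar genes gave 28 higher and 20 lower of 63 (camera adjusted p = 0.285, in the lower direction against the other genes). Their median and mean were above 0. Sugar transport protein 13 (FvH4_4g15150) fell from 68.7 ± 1.29 to 5.52 ± 0.671 FPKM, and sucrose synthase (FvH4_1g09360) rose from 13.6 ± 0.709 to 109 ± 5.75. The sugar pattern also took in 5 phosphofructokinases, enzymes of glycolysis, of which 2 rose and 2 fell. Aroma genes gave 22 higher and 6 lower of 33 (camera adjusted p = 0.109; 0.0276 after quantile normalization, and 0.0276 to 0.252 over the camera alternatives), and pyruvate decarboxylase 2 (FvH4_6g11100) fell from 563 ± 18.9 to 156 ± 7.05 FPKM. The aroma pattern also took in 5 cinnamyl alcohol dehydrogenases, which act in lignin synthesis, of which 3 rose and 1 fell; one, cinnamyl alcohol dehydrogenase 9 (FvH4_1g23790), rose from 36.1 ± 0.784 to 116 ± 3.10 FPKM. The aroma pattern did not take in the vinorine synthase-like and BAHD acyltransferase genes that fell as given above. Nor did it take in a sesquiterpene cyclase gene (FvH4_6g19300), which fell from 396 ± 12.7 to 0.0533 ± 0.0462 FPKM. The aroma counts therefore leave out genes described in other words, and whether these act in aroma was not tested. The list of lignified vascular tissue gave 17 higher and 8 lower of 30, or 9 lower when adjusted over the list alone (camera adjusted p = 0.959). Heat and stress chaperones gave 40 higher and 16 lower of 86 (camera adjusted p = 0.742), and heat shock protein 83 (FvH4_7g30260) was called higher before and lower after rescaling. Defence proteins gave 91 higher and 27 lower of 157, or 92 higher when adjusted over the list alone (camera adjusted p = 0.256; 0.0303 after rescaling to one median, 0.271 after quantile normalization, and 0.0303 to 0.328 over the camera alternatives). The glucan endo-1,3-beta-glucosidase gene FvH4_6g24680 rose from 19.9 ± 0.996 to 427 ± 27.6 FPKM. Cytosolic ribosomal protein genes gave 52 higher and 35 lower of 153, or 51 and 34 when adjusted over the list alone (camera adjusted p = 0.285). After rescaling, 12 were higher and 91 lower (adjusted p = 8.31e-05) and 5 had changed direction: S24-1 (FvH4_1g00370), L19-1 (FvH4_2g26110), S14-2 (FvH4_6g19310), L7a-2 (FvH4_6g53860) and S20-2 (FvH4_7g28020). With quantile normalization 59 were higher and 33 lower, the list test pointed higher and did not pass (adjusted p = 0.224; 8.31e-05 to 0.709 over the camera alternatives), and L23a-1 (FvH4_7g21380) turned from lower to higher, so the direction of this list rests on the scaling. Counts adjusted over the list alone were the same for the sugar, aroma and chaperone lists.

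Of 14 genes of the m6A machinery list, 10 rose and 0 fell in limma, the same as adjusted over the list alone and at an unadjusted p under 0.05 (camera adjusted p = 0.296). The word pattern does not take in FvH4_2g24110, which is described as uncharacterized and whose RNA fell as given above. After rescaling to one median 4 were higher and 1 was lower, and with quantile normalization 2 and 1, so the number of calls rests on the scaling, while no member was called in opposite directions under either. The 4 were a YTH domain-containing family protein 2-like gene (FvH4_3g45840), of a family that binds m6A, at 59.9 ± 1.54 FPKM in WT and 118 ± 4.89 in the mutant, alkB homolog 6 (FvH4_3g46100) and a pair of alkB homolog 8 genes (FvH4_5g24670 and FvH4_2g25440). These alkB homologs entered the list by name, and none is annotated with RNA N6-methyladenosine dioxygenase activity, so a role in m6A is not shown here. The lower one was YTH domain-containing protein 1 (FvH4_5g01140), at 6.29 ± 0.520 FPKM in WT and 6.08 ± 0.867 in the mutant before rescaling. The methyltransferase gene MT-A70-like (FvH4_5g11050) had 10.8 ± 0.313 FPKM in WT and 11.5 ± 0.377 in the mutant (limma adjusted p = 0.312). Among the 10 that rose before rescaling were FvH4_3g29340 and FvH4_4g25170, both described as cleavage and polyadenylation specificity factor subunit CG7185. They too entered by name, and a role in m6A is not shown here. A further alkB homolog 8 gene (FvH4_5g38270) and a YTH domain-containing family protein 2 gene (FvH4_3g13840) did not pass (limma adjusted p = 0.130 and 0.314).

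**Figure D2:**
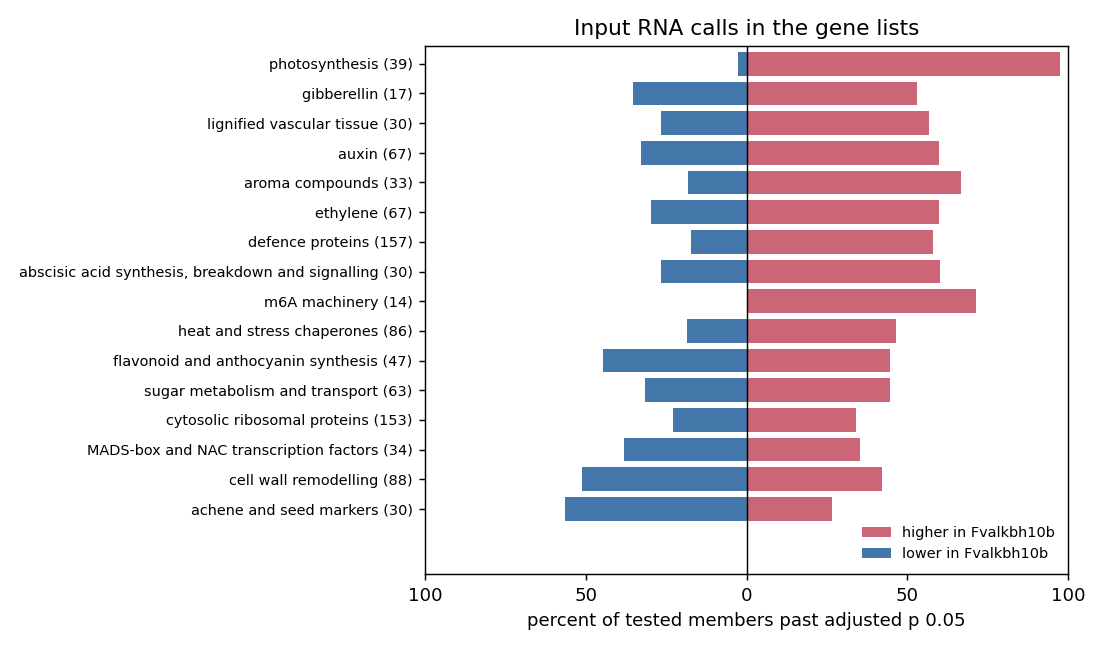
Percent of the tested members of each of the 16 gene lists (number tested in brackets) that passed adjusted p 0.05, to the right for higher and to the left for lower input RNA in Fvalkbh10b. Photosynthesis has 38 of 39 members higher, and in the ethylene, chaperone and ribosomal protein lists some members change direction when the libraries are rescaled to one median, as does 1 ribosomal protein gene with quantile normalization.

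The next comparison asked where m6A lay in each genotype. Most peaks were in 3' untranslated regions (UTRs) in both. The authors listed 23966 peaks in 14032 genes for WT and 24868 peaks in 14758 genes for the mutant. In WT, 13055 peaks (54.5%) lay in the 3' UTR, 7167 (29.9%) in coding exons and 3744 (15.6%) in the 5' UTR. In the mutant these were 13597 (54.7%), 7481 (30.1%) and 3790 (15.2%). The median log2 ratio of IP over input, a value of the authors, was 2.28 over the WT peaks and 2.39 over the mutant peaks, and the median length was 469 and 450 bp. Within the WT list the 3' UTR peaks had a median of 3.01, against 1.32 in coding exons and 1.28 in the 5' UTR. Of the WT peaks 19723 (82.3%) overlapped a mutant peak by at least 1 bp on the same strand, and 19731 mutant peaks (79.3%) overlapped a WT peak. Peaks were present in both genotypes for 13137 genes, in WT alone for 895 and in the mutant alone for 1621. WT peaks without an overlap had a median log2 enrichment of 1.19, against 2.53 for those with one, and 52.3% of them were in coding exons. The lists pool the replicates, so no test between genotypes was made.

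The gene FvH4_2g24110 had a 3' UTR peak in both lists, at 19706358 to 19706582 in WT and 19706458 to 19706582 in the mutant, and a further peak in a coding exon in the mutant list at 19704780 to 19705298. It had no entry among the differential peaks.

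Differential peaks asked which sites carried more or less m6A in the mutant. More were higher than lower. In the authors' deposited table, 4325 peaks in 3753 genes were higher and 1950 peaks in 1778 genes lower at the authors' adjusted p under 0.05. The median log2 change was 0.46 for the higher and -0.53 for the lower peaks of that table. By the authors' deposited table, 3' UTRs held 75.3% of the lower peaks, against 56.3% of the higher ones (odds ratio 2.36, Fisher's exact two-sided p = 4.49e-48, across peaks, which are not independent replicates). Coding exons held 29.7% of the higher and 17.5% of the lower peaks, and 5' UTRs 13.9% and 7.23%. Within classes of enrichment and input expression the odds ratio was 1.14 (95% interval 0.959 to 1.35) with enrichment from the WT list and 7.68 (6.18 to 9.54) with enrichment from the mutant list. The deposited values are rounded to 2 decimals, so peaks near the threshold can fall on either side.

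Among peaks of named proteins with a mean input of at least 1 FPKM, the largest rise in the authors' deposited table was in a coding exon of the mannosidase gene MNS2-like (FvH4_4g07060; chromosome 4, 6471282 to 6471492), with a log2 change of 5.13. In the authors' deposited table a 3' UTR peak of 6-phosphofructokinase 4 (FvH4_7g26950; chromosome 7, 20232212 to 20233573), an enzyme of glycolysis, rose by 4.84, and the RNA of this gene fell with a log2 change of -1.60 ± 0.09 (SE) in limma. A 3' UTR peak of RNA pseudouridine synthase 1 (FvH4_6g07380; chromosome 6, 4429617 to 4429716) had a log2 change of 4.70 in the authors' deposited table. The largest fall under the same limits was -5.01, in the authors' deposited table, for the 3' UTR of a DAYSLEEPER-like zinc finger gene (FvH4_3g04271; chromosome 3, 2434640 to 2445242). The RNA of this gene fell as well, from 4.76, 3.92 and 4.09 FPKM in WT to 0.09 FPKM in 1 mutant library and a listed 0 in the others (limma adjusted p = 2.17e-07), so its peak change is a ratio over almost no mutant input. The DAYSLEEPER-like peak was followed in the authors' deposited table by -4.66 in a coding exon of a C2H2 transcription factor gene (FvH4_6g31360; chromosome 6, 24515276 to 24515400) and -4.53 in the 5' UTR of a TMV resistance protein N-like gene (FvH4_7g21140; chromosome 7, 16982840 to 16983264). The RNA of the TMV resistance protein N-like gene also fell, from 4.22 ± 0.489 to 2.83 ± 0.352 FPKM (limma adjusted p = 0.0111). Apart from 6-phosphofructokinase 4, these genes had a mean input RNA of less than 5 FPKM in each genotype.

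In the authors' deposited table the MT-A70-like methyltransferase gene (FvH4_5g11050) had a higher coding exon peak (chromosome 5, 6237367 to 6239243, log2 change 0.46). Its 3' UTR peak was listed there at -0.39 and did not pass (authors' adjusted p = 0.1). Of 13 m6A machinery genes with a peak, 3 had a higher peak alone and 1 a lower peak alone. The lower peak was in a coding exon of an alkB homolog 8 gene (FvH4_5g24670), at -0.66 in the authors' deposited table. The 3' UTR peaks of a chlorophyll a-b binding protein (FvH4_5g14770) and of photosystem I subunit VI (FvH4_6g31740) were lower by the authors' deposited table, at -2.05 and -1.07, while their RNA rose from 11.9 ± 2.06 to 154 ± 9.01 and from 2.44 ± 0.170 to 63.9 ± 7.61 FPKM. By the authors' deposited table the 3' UTR peaks of beta-galactosidase 3 (FvH4_1g12350), pyruvate decarboxylase 2 (FvH4_6g11100), protein phosphatase 2C 24 (FvH4_3g37010) and a legumin A-like gene (FvH4_2g21430) were higher, with log2 changes of 1.04 for beta-galactosidase 3, 1.72 for the phosphatase and 2.12 for the legumin. The RNA of these 4 genes fell, for beta-galactosidase 3 from 134 ± 3.18 to 38.3 ± 1.06 FPKM and for the legumin from 16.3 ± 0.880 to 6.55 ± 0.861. Not all genes went opposite ways: a probable polygalacturonase (FvH4_5g03040) had a higher 3' UTR peak in the authors' deposited table and RNA that rose from 2.75 ± 1.07 to 14.8 ± 0.403 FPKM. Of 137 cytosolic ribosomal protein genes tested in the input RNA and with a peak, 57 had higher peaks alone (41.6%, odds ratio 2.19, Fisher's exact adjusted p = 4.54e-04 over 32 tests). Lower peaks alone were held by 22 of them (16.1%, odds ratio 1.58, Fisher's exact adjusted p = 0.340). Over all 13573 tested genes with a peak, 3354 had a higher and 1471 a lower peak alone. These list tests were not matched on expression. Median input was 15.1 FPKM with a higher peak and 11.5 with a lower peak, against 7.38 with a peak that was not differential. Expression level can therefore enter the list counts. Of 32 photosynthesis genes tested in the input RNA and with a peak, 6 had a lower peak alone (odds ratio 1.90, Fisher's exact adjusted p = 0.518). Only 1, the photosystem II protein Psb28 (FvH4_2g20470), had a higher peak alone (odds ratio 0.098, Fisher's exact adjusted p = 0.0289). Chlorophyll a-b binding protein 5 (FvH4_5g26480) also had a higher 3' UTR peak in the authors' deposited table but was outside this count, since its mean input RNA was under 1 FPKM. No other list passed in either direction.

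**Figure D3:**
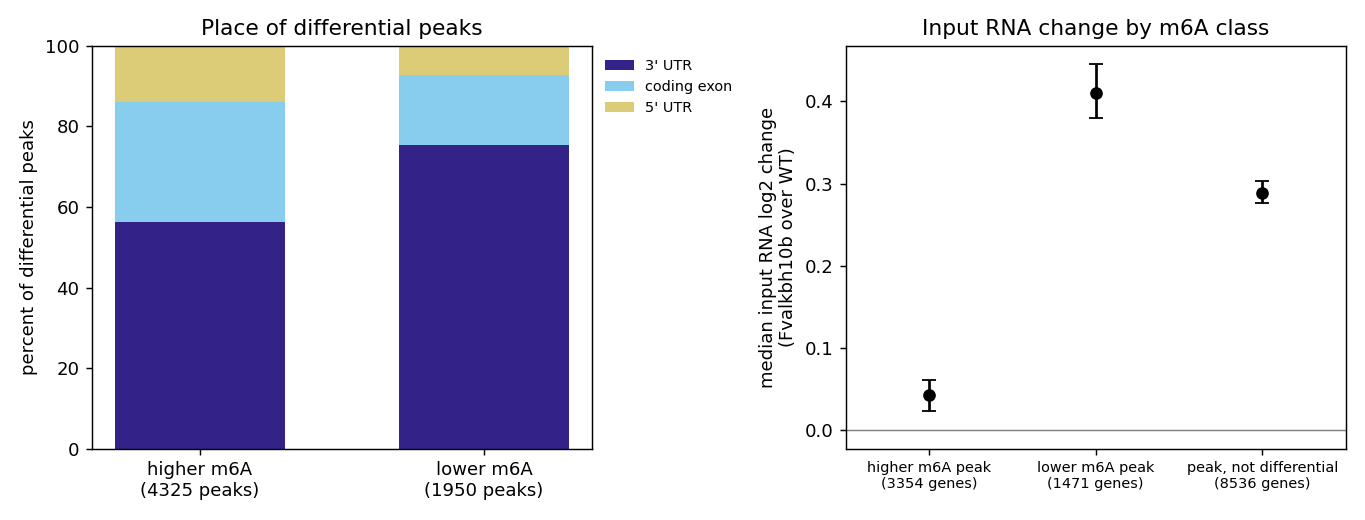
The left panel plots the percent of the 4325 higher and 1950 lower differential peaks in each part of the transcript, and the right panel the median log2 change of input RNA, Fvalkbh10b over WT, for genes with a higher peak alone, a lower peak alone or a peak that is not differential, with 95% bootstrap intervals. Lower peaks have the larger 3' UTR share and their genes the highest median RNA change.

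The last comparison asked whether genes with changed m6A also changed in RNA level. Relative to genes with a peak that was not differential, RNA was lower with a higher peak and higher with a lower peak. The relation was weak across 5981 differential peaks in tested genes (Spearman rho -0.27, across peaks, which are not independent replicates). Without that reference, genes with a higher peak had a median just above 0, and more of them rose than fell. Genes with a peak in the mutant list alone had higher RNA in the mutant. Genes with a lower peak alone (1471 genes) had a median RNA log2 change of 0.41, with a 95% bootstrap interval of 0.38 to 0.45. Genes with a higher peak alone (3354 genes) had 0.04, with an interval of 0.02 to 0.06, and genes with a peak that was not differential (8536 genes) had 0.29. After rescaling to one median these were 0.16, -0.22 and 0.05. Each of the 3 contrasts gave a two-sided permutation p of 1e-05, the smallest that 100000 resamples can give, with the same value after adjustment. These tests are across genes, which are not independent replicates. Median input was 15.1 FPKM for genes with a higher peak, 11.5 with a lower peak and 7.38 with a peak that was not differential. The sets were not matched on it. Over tested genes the median log2 ratio of mean FPKM was 0.31 at 5 to 10 FPKM and 0.23 at 10 to 20. Expression level can therefore enter the contrast of higher with not differential peaks and the overlap counts below. Among genes with a lower peak 951 rose (64.6%) and 116 fell (7.89%). Among those with a higher peak 1189 rose (35.5%) and 1041 fell (31.0%). Falling RNA was shared with a higher peak by 1041 genes, where 612 were expected by chance from 13573 genes with a peak (odds ratio 2.75, Fisher's exact adjusted p = 1.68e-98). Rising RNA was shared with a lower peak by 951 genes, where 715 were expected (odds ratio 2.09, adjusted p = 5.41e-39). By presence of a peak the order was the other way. The median RNA log2 change was 0.61 for 768 tested genes with a peak in the mutant alone (95% bootstrap interval 0.55 to 0.69), 0.29 for 625 with a peak in WT alone (0.21 to 0.38) and 0.23 for 12180 with a peak in both. The first set differed from each of the others (two-sided permutation adjusted p = 1.5e-05, from the smallest p that the resamples can give), and WT alone did not pass against both (adjusted p = 0.631). After rescaling to one median these medians were 0.42, 0.06 and -0.02. This comparison was chosen after seeing the data. Genes with a peak in the mutant alone had a low median input, 1.80 FPKM in WT and 3.85 in the mutant. With a peak in both it was 8.9 and 10.8, and with one in WT alone 5.17 and 6.07. Low genes shifted more among tested genes: the median log2 ratio of mean FPKM was 0.72 at 1 to 2 FPKM and 0.47 at 2 to 5. The contrast by presence was not matched on expression, so it cannot be told apart from that trend.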

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

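The test on peaks with enrichment above the median of their list, the rescaled RNA comparison, the RNA comparison by peak presence and the seed list without GEM-like proteins were chosen after seeing the data. Leaving out 1 library in turn gave 9867 to 9960 called genes, 6995 to 7151 higher and 2789 to 2880 lower, and at 2-fold 2140 to 2237 higher and 1005 to 1030 lower; 3 to 5 lists passed, and 5 did without Fvalkbh10b input replicate 2, where the flavonoid and the MADS-box and NAC lists also passed (adjusted p = 0.0459 each). Without Fvalkbh10b input replicate 1 the flavonoid list (0.0477) and without WT input replicate 3 the MADS-box and NAC list (0.0475) passed. The gap in median RNA change between genes with lower and higher peaks was 0.358 to 0.389; it reversed to -0.323 between genes with a peak in WT alone and in the mutant alone. Rescaling to one median gave 4800 higher and 5011 lower genes, and quantile normalization 4869 and 4625, because both centre the libraries. Requiring 2-fold left 3184 genes, 2173 higher and 1011 lower. By q in the authors' deposited table, genes numbered 6068 with a change above 0, 4644 below and 52 at 0. Since the test in the authors' deposited table is centred away from 0, 612 of the 6068 lie below its centre of 0.28, which 5456 exceed and 5308 do not reach. Among the significant calls in the authors' deposited table, 3709 were higher and 1445 lower. At a mean of at least 5 FPKM, with fewer genes tested, 1260 were higher by 2-fold. Of the lists, 0 passed with an estimated correlation, 5 after median rescaling and 15 by fry, which does not compare a list with other genes. Replicate numbers did not pair the libraries: correlations of same-numbered deviations were 0.035, -0.031 and 0.029, and libraries correlated best with their own number for numbers 1 and 3 but not 2. With the replicate block 10423 genes and 5 lists passed, the flavonoid and the MADS-box and NAC lists among them (adjusted p = 0.0479 each). The share of WT peaks overlapped was 68.8% with reciprocal overlap of 50%, 95.6% by gene, 85.4% at a fold enrichment of at least 2 and 87.0% above the median enrichment; for mutant peaks it was 66.3%, 91.6%, 77.8% and 83.8%. Differential peaks in the authors' deposited table numbered 2616 higher and 962 lower at adjusted p under 0.01, and 710 and 449 with a log2 change of at least 1; 3013 lower were listed in all. The share of higher peaks in the authors' deposited table was 66.1% of all listed, 73.1% under 0.01 and 61.3% with a log2 change of at least 1. Where no reason is given, the cause was not tested. Of the genes taken by the naming rule, none reversed past the threshold under the alternatives run. Other list members did: RAP2-3, heat shock protein 83 and 5 ribosomal protein genes after median rescaling, and L23a-1 with quantile normalization. Not run were motifs (no genome), exon blocks, transcripts (the table is by gene), and a split of peaks by p, since nearly all p are listed as 0. The ALKBH10B level by name had no gene. The unknown depth limits all low genes.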

Other observations

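The pathway tests were chosen after the differences were seen, as were the tests of sample splits, of expression classes, of noise in genes changed by 2-fold and of peak presence, and the use of each list alone for classes of enrichment. The pathway annotation of the authors' table gave further groups, some of which, such as plant hormone signal transduction, overlap the fixed lists in theme. Among genes higher in the mutant by at least 2-fold, brassinosteroid biosynthesis held 9 of 15 genes (against 13.5% of annotated genes; Fisher's exact one-sided adjusted p = 9.71e-04 over 117 pathways), and plant hormone signal transduction 62 of 259 (adjusted p = 8.77e-05); 30 of these 259 were lower by at least 2-fold (adjusted p = 0.0480). Among genes lower by at least 2-fold, sesquiterpenoid and triterpenoid biosynthesis held 10 of 22 (adjusted p = 2.57e-05), ABC transporters 16 of 68 (adjusted p = 3.48e-04) and fatty acid biosynthesis 9 of 33 (adjusted p = 0.00678). Phenylpropanoid biosynthesis passed both ways, with 26 of 112 genes higher (adjusted p = 0.0482) and 25 lower (adjusted p = 6.78e-06). Among genes with higher m6A, oxidative phosphorylation held 47 of 99 (47.5%, against 25.6%; adjusted p = 2.12e-04 over 115 pathways). A metallothionein-like gene (FvH4_3g20030) had 56286 to 57559 FPKM in the WT libraries and 102370 to 121590 FPKM in the mutant libraries, where it took 20.4% to 23.3% of the summed FPKM.

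Most genes called in the input RNA were higher in the mutant. One scale factor per library would shift all classes of expression alike, but the median log2 ratio of mean FPKM was 0.72 among genes of 1 to 2 FPKM and 0.08 among those of at least 50, a difference of 0.645. One factor therefore does not account for the whole pattern, and whether it accounts for part stays open, since rescaling to one median fixes the balance of directions by its centring. Genes listed at 0 numbered 2906 to 3029 in the WT libraries and 2104 to 2151 in the mutant libraries, and the depth of each is unknown. Only 1 of the 10 splits of the 6 libraries, the real one, called as many as 10505 genes. The highest of the others called 0. Every other split mixes the genotypes within its groups, so their difference enters the spread and few calls follow from the design. In addition, 10 splits are too few for a share under 0.05, so the splits decide nothing. A difference in fruit development between genotypes picked at one age stays open and was not tested.

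RNA and m6A changes tended to go opposite ways for differential peaks, relative to genes with a peak that was not differential. Input noise enters both measures with opposite sign, and the sampling variance of the RNA change was 6.29% of the size of their covariance, but that covariance is over peaks chosen for their change, so shared noise cannot be told apart over all of these genes. Among 807 genes whose RNA changed by at least 2-fold, the odds ratio of higher RNA between genes with higher and lower peaks was 0.0565 (95% interval 0.0354 to 0.0903) and the smallest RNA change was 4.56 standard errors, so shared noise is unlikely to be the whole source there. Lower enrichment at higher expression cannot be told apart either. The slope of enrichment on log2 expression was -0.0164 in WT 3' UTR peaks (95% interval -0.0260 to -0.00627). In the mutant it was 0.00777, with an interval that holds 0. Over differential 3' UTR peaks the slope of peak change on RNA change was steeper, at -0.279, but those peaks were chosen for their change. A trend across genes also need not hold within a gene. By presence of a peak in one list alone the gap in median RNA change was -0.32, the other way, between gene sets of unlike expression level. Neither the cause of that nor any effect of m6A on RNA level was tested.

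Lower peaks lay in the 3' UTR more often than higher peaks. Peaks there are stronger, and could differ in how easily a change is called. Within 25 classes of enrichment in the WT list and of input expression the odds ratio was 1.14 (95% interval 0.959 to 1.35), and with enrichment in the mutant list it was 7.68 (6.18 to 9.54). The explanation cannot be told apart from a difference in place, because the enrichment in either genotype is tied to the change itself and the 2 lists give different answers. A difference in antibody enrichment between the genotypes was not tested, and no biological explanation was tested.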
